A study of Mus musculus with 6 samples.

How the data were processed

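Total RNA from homogenised whole mouse lung was labelled with Cy3 and hybridised to 6 Agilent 1-colour whole-genome arrays, per the labels. The arrays form 6 groups of 1 array each: wild type (WT) C57BL/6 mice, mice labelled FcRg KO and mice labelled FceRIa KO, each given PBS or mouse histamine-releasing factor (HRF, the secreted form of the product of Tpt1) through the nose. All 6 arrays lie on 1 slide that was scanned in a single run, so no slide or scan batch could be compared. The labels do not say whether an array holds RNA of a single mouse or of pooled mice, nor the dose or the time after the challenge. Wherever arrays of different groups stand in for replicates, a p-value measures the spread between these arrays.

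Spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, per the file headers, which also name a design annotated on the mouse assembly mm9. The deposited processed signal is an intensity that the scanner software had background-subtracted and detrended within each array, per the file headers, without scaling between arrays. The deposited spot and local background intensities are the raw medians. A deposited value table of the series holds log2 values with unstated centring and scale. Set against the scanner files, differences between its columns of the same genotype correlated with those of the scaled processed signal across probes with r of 0.998 in WT, 0.997 on the arrays labelled FcRg KO and 0.997 on those labelled FceRIa KO. The slopes were 1.00, 0.998 and 1.00, so its direction matches that of the scanner files. Its column medians were 0.10 for WT PBS and 0 for each of the other arrays, and the exact value on which each probe was centred stays unknown.

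The main value was log2 of the processed signal minus log2 of the array's 75th percentile of it, so that 0 marks the 75th percentile. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged. Of 55681 probes, 32335 carried a RefSeq accession and 26056 were named through it with the RefSeq gene table of assembly GRCm38.p6, which gave 19752 genes. The other 29625 probes are unnamed here. For the 5270 genes with several probes, the probe with the highest mean over the arrays was used. No coordinates of that table are given, since its assembly is not that of the array design, and it served for names and for which genes neighbour each other within 10 Mb. A gene was compared when its probe was well above background on at least 1 of the arrays compared. Where the probe was not well above background on the only array of a group, the ratio is a bound against the higher of its own signal and the lowest signal among probes well above background there, written "at least N-fold".

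With 1 array per group, no test was possible within a genotype. The HRF response was the log2 ratio of the HRF to the PBS array, genes with a ratio of at least 2-fold were counted, and the PBS arrays of different genotypes were counted the same way as background. Gene lists were described by the percentile of their median ratio among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays that takes no account of genes varying together, and the same was counted between PBS arrays after the data were seen. A list was called above or below the random lists past percentiles 97.5 or 2.5. The average HRF effect and the difference of each labelled knockout from WT were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype and challenge as additive terms, 2 residual degrees of freedom, Benjamini-Hochberg 0.05). The residual of this fit is the genotype by challenge interaction, so its p-values do not measure the spread between mice of a group. Lists were tested in the same fit with camera, with a preset correlation of 0.01 and with an estimated one. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

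The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The 47 lists cover Fc receptors, immune, epithelial, vascular and stromal cell types, neighbouring tissues, inflammatory and type 2 pathways, and sex-linked genes. The last had 2 measured members, under the minimum of 3 for a median. The rule named the Fc receptor genes and Tpt1, the 10 highest and 10 lowest ratios in WT and the 6 highest and 6 lowest in each labelled knockout, up to 3 bounds each way, and the 8 highest and 8 lowest differences of response. It also named up to 10 genes each way per limma effect, or the 3 with the smallest p where fewer than 3 passed, up to 4 members per list, and genes within 10 Mb of Fcer1g or Fcer1a at least 2-fold off WT on both arrays of a labelled knockout. The text leaves out 3 genes that the rule names. Alternatives were normexp background correction with an offset of 50 and quantile normalization, the deposited value table, scaling on the median, a stricter and no filter on dim probes, the mean of all probes of a gene, other model terms, another prior, and leaving out arrays. The mean spot signal is not among the columns used here, so normexp ran on the median spot signal. Counts of genes with a mean log2 of -3 or more, called bright here, comparisons with another PBS array, and a limma term for the response of 1 genotype against the other 2, with 1 residual degree of freedom, were added after the data were seen.

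The steps were tested on simulated data. Of 50 genes planted at each size among 17608, limma recovered 64% at a log2 effect of 1, 90% at 2, 98% at 3 and 100% at 4 for the HRF effect, with 8 false calls. For the arrays labelled FcRg KO against WT the shares were 38%, 86%, 98% and 100%, and for those labelled FceRIa KO 34%, 92%, 96% and 96%. The simulated noise was independent between genes and held no genotype by challenge interaction. These shares therefore check the code and do not give the power of the real test. Of 100 unshifted random lists of 15 genes in a simulated WT pair, 2 came out above and 3 below, and 99 of 100 came out above at a planted shift of 0.50. The simulated HRF array was the WT PBS array plus noise independent between genes. These rates therefore do not carry over to lists whose genes vary together.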

Results

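Gene expression in whole lung was measured on 6 arrays, 1 for each of 6 groups: WT, FcRg KO and FceRIa KO mice challenged through the nose with PBS or with HRF, a protein secreted during allergic reactions that can bind IgE. The FcRg chain, encoded by Fcer1g, carries the signal of several Fc receptors, and the FceRIa chain, encoded by Fcer1a, binds IgE in the high-affinity IgE receptor. Each array held 59305 spots other than controls, and between 67.5% and 79.6% of them were well above background. The 75th percentile of the processed signal was 1622 for WT PBS, 1563 for WT HRF, 1605 and 1300 for PBS and HRF of the arrays labelled FcRg KO, and 1593 and 1197 for those labelled FceRIa KO. No spot was saturated. There are no replicates, so no ratio between 2 arrays has a replicate check, and the number of arrays limits the precision.

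The targeted genes were measured first. Fcer1g stood at log2 3.93 and 4.61 on the WT PBS and HRF arrays, 4.14 and 4.32 on the arrays labelled FcRg KO, and 4.07 and 4.45 on those labelled FceRIa KO, where 0 is the 75th percentile of an array. The arrays labelled FcRg KO differed from WT by -0.04 on average (limma adjusted p = 0.917). Fcer1a stood at -4.48 and -4.19 in WT, -4.70 and -4.38 on the arrays labelled FcRg KO, and -0.90 and -1.16 on those labelled FceRIa KO, a level 9.90-fold above WT that did not pass the threshold (log2 3.31, SE 0.19, limma adjusted p = 0.075, higher on 2 of 2 arrays). Neither label is borne out by a lower level of its gene. Whether these probes lie within the deleted parts is not known here, and a probe outside a deleted part checks nothing. The groups are therefore named by their labels throughout. Ms4a2, the beta chain of the IgE receptor, was not well above background on any array, and Tpt1, which encodes HRF itself, lay between 7.72 and 8.15.

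**Figure D1:**
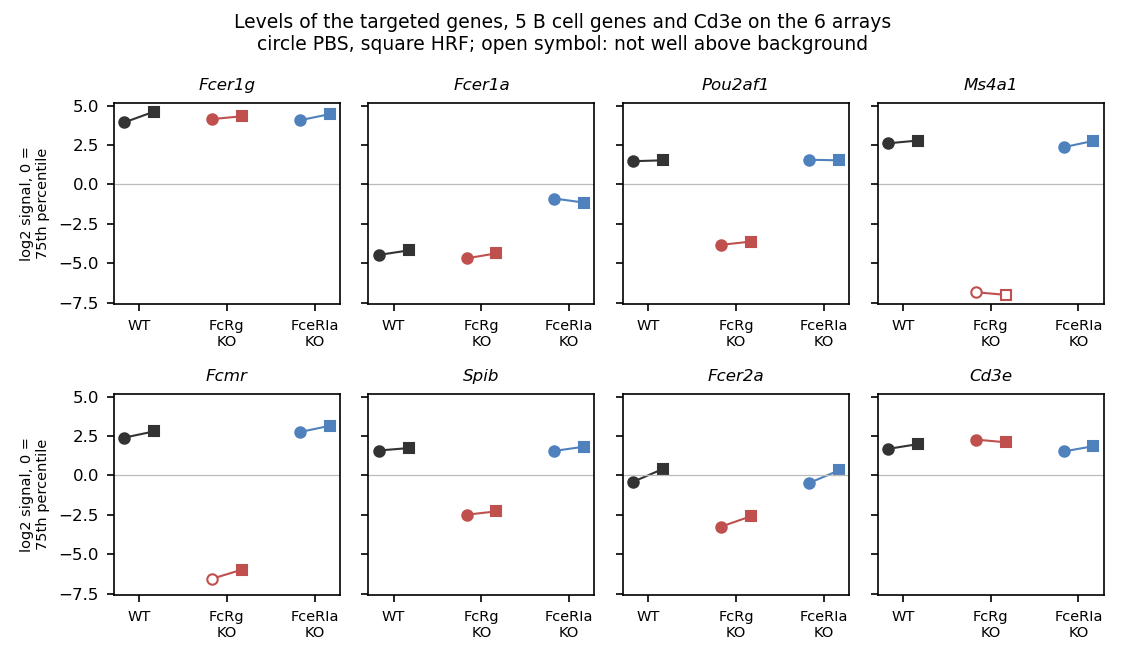
Levels of Fcer1g, Fcer1a, 5 B cell genes and Cd3e on the 6 arrays, as log2 signal relative to the 75th percentile of each array (y axis) by genotype label (x axis), with a circle for the PBS array, a square for the HRF array and an open symbol where the probe was not well above background. Fcer1a lies at -0.90 and -1.16 on the arrays labelled FceRIa KO, Ms4a1 and the other B cell genes lie lowest on the arrays labelled FcRg KO, and Cd3e, a T cell gene drawn after its values were seen, lies between 1.51 and 2.27 on the 6 arrays.

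In WT lungs, the HRF array carried far higher levels of chemokines and cytokines than the PBS array. Cxcl5, which attracts neutrophils, was 108-fold higher (log2 6.76). The cytokines Il17a (5.30), Il6 (4.80) and Il17f (4.39), the monocyte chemoattractants Ccl7 (4.77) and Ccl2 (4.35), and Ccl24 (5.08), which attracts eosinophils, were among the 10 highest measured log2 ratios. Il13, a central type 2 cytokine, was not well above background on the PBS array and was at least 56.9-fold higher. In all, 407 genes were at least 2-fold higher and 307 at least 2-fold lower among 17437 compared.

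Several gene groups were higher together in WT. The type 2 cytokine and effector list had a median log2 ratio of 1.90, with 21 of 29 genes at least 2-fold higher, among them Ccl11 (3.52) and Ccl17 (2.89). The neutrophil and monocyte chemokine list had a median of 1.86 (10 of 16 genes), and the mucous and goblet cell list 1.53 (9 of 16), with Slc26a4, an epithelial anion exchanger, at 4.11, Itln1 at 2.80 and Clca1 at 2.17. The NF-kB and toll-like receptor list had a median of 1.43 (29 of 41), with Saa3 at 3.57, Saa2 at 3.11 and the long pentraxin Ptx3 at 3.06. The inflammatory cytokine list had a median of 1.35 (13 of 25), with Csf3 at 3.04, and the acute phase and antimicrobial list 1.07 (16 of 28). Each of these medians lay above all 10000 random lists.

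Leukocyte and interferon lists followed at smaller sizes. Median log2 ratios were 0.79 for neutrophil markers (Il1r2 2.41, Cxcr2 2.29), 0.78 for ILC2 and type 2 lymphocyte genes (Il5 3.93, Il2ra 2.45, Il4 2.17), 0.63 for Fc receptors, 0.62 for interferon-inducible chemokines and GTPases (Cxcl10 3.17, Cxcl9 2.33), 0.50 for T cell markers and 0.49 for dendritic cell markers (Batf3 2.41, Cd209a 1.96). Among Fc receptors, the inhibitory receptor Fcgr2b stood at 1.95, Fcgr3 at 1.18, Fcgr1 at 0.91 and Fcgr4 at 0.74. Medians of 0.42 for complement genes, 0.37 for immediate early genes, 0.30 for monocyte and interstitial macrophage markers, 0.28 for eosinophil markers, 0.28 for plasma cell and immunoglobulin genes, 0.28 for type I interferon genes, 0.25 for hypoxia and stress response genes, 0.24 for alveolar macrophage markers, 0.18 for NK cell markers, 0.17 for B cell markers and 0.15 for histamine, leukotriene and prostaglandin genes also lay above the random range. Of the 46 lists, 23 lay above and 9 below in WT, 18 and 9 on the pair labelled FcRg KO, and 22 and 7 on the pair labelled FceRIa KO. Between PBS arrays, counted after the data were seen, 11 lay above and 9 below on that labelled FcRg KO against WT, 4 and 13 on that labelled FceRIa KO against WT, and 11 and 21 on that labelled FceRIa KO against that labelled FcRg KO. A median outside the random range was thus common between PBS arrays of different genotype labels, without any HRF. Genes of a list that vary together and differences between genotypes cannot be told apart there. Outside the lists, the lectin Cd209e stood at 5.07 and Aldh1a3, which makes retinoic acid, at 4.33, while E-selectin (Sele) was at least 18.6-fold higher and Ms4a13 at least 20.1-fold, although a second Ms4a13 probe gave 0.02.

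The lists below the random ones in WT were circadian clock genes (median -0.48, with Per3 at -1.11 and Nr1d1 at -0.97), smooth muscle markers (-0.39), platelet and megakaryocyte genes (-0.39), atrial and pulmonary vein cardiac muscle markers (-0.36), erythroid genes (-0.28), ciliated cell markers (-0.24), adipocyte markers (-0.12), glucocorticoid response genes (-0.12) and alveolar type 1 cell markers (-0.09). Against WT PBS, the clock list also stood at -0.39 on the PBS array labelled FcRg KO and -0.14 on that labelled FceRIa KO. Its low ratio in WT may therefore rest partly on a high level on the WT PBS array, and whether HRF lowers these genes was not tested. The lowest single ratios were those of Sprr2j-ps (-2.61), the glucocorticoid-responsive gene Zbtb16 (-2.59), Syce1 (-2.51), Ncam2 (-2.36), Dnajb8 (-2.13), Upk3bl (-2.11), Vmn1r197 (-2.05), Mup5 (-1.92), Mup20 (-1.91) and Entpd8 (-1.80). Spry3, Calb1 and Catsperb were at least 16.1-fold, 15.5-fold and 13.3-fold lower. Of the 307 lower genes, 85.3% had a mean log2 under -3, against 25.1% of the genes compared. Lists within the random range are given with the further observations.

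The share of higher genes in WT depended on the processing. It was 57.0% in the main setting, 37.0% with no filter on dim probes (542 higher, 921 lower), 47.6% with the deposited value table (489 higher, 538 lower), 68.1% with scaling on the median and 89.7% with normexp (305 higher, 35 lower). Between PBS arrays of different genotypes, the same count gave 121 higher and 528 lower on the array labelled FcRg KO than in WT, 93 higher and 501 lower on that labelled FceRIa KO than in WT, and 195 higher and 189 lower on that labelled FceRIa KO than on that labelled FcRg KO. These PBS counts depended on the processing as well. With normexp, 83 genes were higher and 82 lower on the array labelled FcRg KO than in WT, and 37 and 40 on that labelled FceRIa KO. With the deposited value table the counts were 168 and 1075, and 124 and 1216. Among bright genes the WT response held 287 higher and 45 lower genes, against between 23 and 80 each way between PBS arrays.

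**Figure D2:**
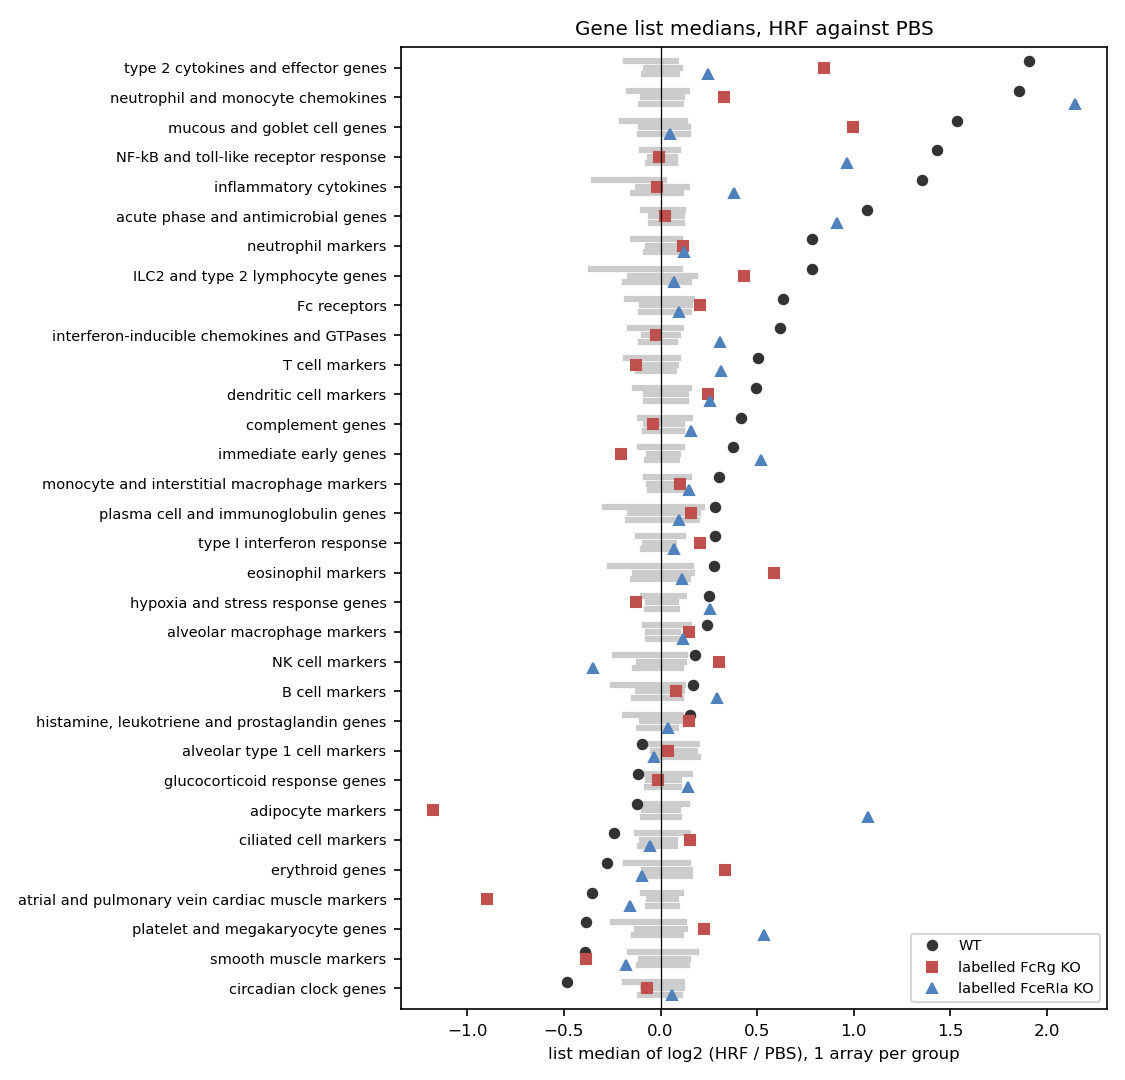
Median log2 ratio of HRF to PBS (x axis) for each of the gene lists outside the random range in WT (y axis), with circles for WT, squares for the arrays labelled FcRg KO and triangles for those labelled FceRIa KO, 1 array per group. Grey bars span the random range, and the chemokine list lies at 1.86 in WT, 0.33 on the pair labelled FcRg KO and 2.14 on the pair labelled FceRIa KO.

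On the arrays labelled FcRg KO, the HRF array carried higher type 2 and mucous genes than the PBS array, with smaller ratios of cytokine and chemokine genes than in WT. The type 2 list had a median of 0.85 (10 of 29 genes at least 2-fold higher) and the mucous list 0.99 (7 of 15), with Ccl24 at 3.77, Tff1 at 3.38, Arg1 at 3.14, Clca1 at 1.89 and Slc26a4 at 1.99. Il13 was at least 4.88-fold higher and Retnlb at least 5.98-fold. The inflammatory cytokine list stood at -0.02, the NF-kB list at -0.01, the acute phase list at 0.02 and the interferon-inducible chemokine list at -0.02, all within the random range, with Il6 at -0.28, Cxcl1 at -0.75 and Ccl2 at -0.06. The chemokine list, with a median of 0.33, lay above all 10000 random lists, and none of its 15 genes reached 2-fold. Eosinophil markers stood at 0.59, with the granule protein genes Prg2 at 1.57 and Epx at 1.42, and basophil markers at 0.32, with Mcpt8 at 2.12. Levels on the PBS array labelled FcRg KO were below those of WT PBS for Mcpt8 (-6.15 against -4.18), Epx (-5.43 against -4.15) and Prg2 (-1.20 against -0.56), and HRF levels of Mcpt8 (-4.03 against -3.93) and Epx (-4.02 against -3.88) were near those of WT HRF, while that of Prg2 was above it (0.36 against -0.28). Against WT, the eosinophil list as a whole stood at 0.12 on the PBS array and 0.33 on the HRF array. The neutrophil granule genes Mpo (-1.96 against -0.04) and Camp (1.57 against 2.65), chosen after their values were seen, were also lower on that PBS array. The neutrophil list as a whole went the other way there, at 0.35 against WT on the PBS array and -0.12 on the HRF array.

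The lowest list medians on the pair labelled FcRg KO were those of fat and heart muscle genes. Adipocyte markers had a median of -1.18 (10 of 19 genes at least 2-fold lower), led by Ucp1, which makes brown fat produce heat, at -6.44, Cidea at -3.30 and Elovl3, at least 12.1-fold lower. Atrial and pulmonary vein cardiac muscle markers had a median of -0.90 (10 of 30), with the natriuretic peptide gene Nppb at -2.99. Against WT, the adipocyte list stood at 0.47 on the PBS array and -0.49 on the HRF array, and the cardiac list at 0.53 and 0.04. These low ratios therefore rest partly on a higher level on the PBS array, and whether HRF lowers these genes was not tested. Cyp26b1, which degrades retinoic acid, stood at -5.56, Afm at -3.50 and Gys2 at -2.96, while Slc34a3 was at least 42.9-fold and Cd163 at least 14.3-fold lower. Medians of -0.45 for skeletal muscle, -0.39 for smooth muscle, -0.21 for immediate early genes, -0.19 for oesophagus and squamous epithelium, -0.13 for T cell markers, -0.13 for hypoxia genes and -0.12 for nerve and Schwann cell genes also lay below the random lists. Medians of 0.45 for cell cycle genes, 0.43 for ILC2 genes, 0.33 for erythroid genes, 0.30 for NK cell markers, 0.24 for dendritic cell markers, 0.22 for platelet genes, 0.21 for Fc receptors, 0.20 for type I interferon genes, 0.20 for alveolar type 2 cell markers, 0.15 for ciliated cell markers, 0.15 for alveolar macrophage markers, 0.14 for histamine and lipid mediator genes and 0.12 for neutrophil markers lay above them. Other high single genes were Ezhip (3.58), Fbp1 (3.23) and the macrophage elastase Mmp12 (2.67), and Olfr13 was at least 6.23-fold higher.

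In number, 128 genes were at least 2-fold higher and 196 lower of 16595 compared on the pair labelled FcRg KO. Of the calls, 39.5% were higher, 48.7% with no filter and 24.5% with normexp, where 26 genes were higher and 80 lower. Among bright genes 31 were higher and 86 lower, against between 23 and 80 each way between PBS arrays.

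On the arrays labelled FceRIa KO, the HRF to PBS ratios of neutrophil and monocyte chemokines were large, as in WT, and those of type 2 and mucous genes were smaller than in WT. The Cxcl5 level on the HRF array was 1.5, against 4.5 in WT. The chemokine list had a median of 2.14 (9 of 16 genes at least 2-fold higher), with Cxcl5 61.2-fold higher (log2 5.93), Cxcl3 at 5.70, Cxcl1 at 5.07, Ccl7 at 3.66, Ccl2 at 3.39 and Cxcl2 at least 32.2-fold higher. The NF-kB list stood at 0.96 (19 of 41) and the acute phase list at 0.91 (13 of 28), with Saa3 at 4.52, Saa2 at 4.34 and Il6 at 4.16. The type 2 list had a median of 0.24 (6 of 29), with Ccl24 at 1.21, Il5 at 0.90, Il4 at 0.32 and Il13 at least 1.23-fold higher. The mucous list stood at 0.05, within the random range, with Clca1 at -0.41 beside Slc26a4 at 3.60.

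Fat genes went the other way than on the pair labelled FcRg KO: adipocyte markers had a median of 1.07 (10 of 18 genes at least 2-fold higher), with Ucp1 at 2.77 and Lep at 1.48. Against WT, the adipocyte list stood at -0.28 on the PBS array and 0.65 on the HRF array. Medians of 0.54 for platelet genes, 0.52 for immediate early genes, 0.39 for mesothelial cell markers, 0.38 for inflammatory cytokines, 0.31 for T cell markers, 0.31 for interferon-inducible chemokines, 0.29 for B cell markers, 0.26 for hypoxia genes, 0.25 for dendritic cell markers, 0.21 for alveolar type 2 and 0.21 for club cell markers, 0.16 for complement genes, 0.15 for monocyte markers, 0.14 for glucocorticoid genes, 0.12 for neutrophil markers, 0.11 for alveolar macrophage markers and 0.07 for type I interferon genes lay above the random lists. Without the 2 members that the adipocyte list also holds, Fabp4 and Cidec, the alveolar macrophage median was 0.06, within the random range. Those of -0.39 for cell cycle genes, -0.35 for NK cell markers, -0.18 for smooth muscle, -0.16 for cardiac muscle, -0.16 for fibroblast and matrix genes, -0.10 for erythroid genes and -0.04 for alveolar type 1 cells lay below, the last turning to 0.01 with scaling on the median and 0 in the deposited value table. Cyp26b1 (-2.93), Olfr738 (-2.37), Slc24a2 (-1.82), Prok2 (-1.72), Dpp10 (-1.59) and Trub1 (-1.56) had the lowest ratios, and Lin28b, Mcpt1 and Lyg1 were at least 49.1-fold, 13.5-fold and 9.03-fold lower. Rhobtb2 stood at 5.38 through a high level on the HRF array, and Olfr727 was at least 12.7-fold higher.

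In number, 243 genes were at least 2-fold higher and 75 lower of 16315 compared on the pair labelled FceRIa KO, and 115 and 11 among bright genes. Of the calls, 76.4% were higher, 65.8% with no filter, 69.5% with the value table and 87.9% with normexp, where 116 genes were higher and 16 lower.

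The labels name knockouts that would ask whether the response to HRF needs these receptor chains. Neither label is borne out by a lower level of its gene here. Of the bright genes near Fcer1a, 13 of 152 (8.55%) were at least 1.5-fold off WT on the arrays labelled FceRIa KO. The share over all bright genes was 0.81%, and that near Fcer1a lay at percentile 99.1 of all centres. On the arrays labelled FcRg KO it was 2 of 152 (1.32%), against 1.19% of all bright genes. The arrays labelled FceRIa KO thus differed from WT in the region that holds Fcer1a and Fcer1g, and those labelled FcRg KO hardly did. What this says of the labels was not tested. In limma with a term for the response of WT against the shared response of both labelled knockouts, added after the data were seen and with 1 residual degree of freedom, 0 genes were higher and 0 lower past the threshold, with 1527 at an unadjusted p under 0.05 and a lowest adjusted p of 0.570. The same term for the response on the pair labelled FcRg KO gave 0 and 0 (1028 unadjusted) and for that on the pair labelled FceRIa KO 0 and 0 (608 unadjusted). The differences of response below are therefore values that passed no test. WT and the pair labelled FceRIa KO shared 87 genes at least 2-fold higher, where independent lists would share 5.24, and WT and the pair labelled FcRg KO shared 28, against 2.84. The pairs labelled FcRg KO and FceRIa KO shared 10, against 1.38. Among genes at least 2-fold lower the order differed. WT shared 14 with the pair labelled FcRg KO, against 2.49, and 5 with the pair labelled FceRIa KO, against 0.67. The 2 labelled knockouts shared 2, against 0.56. Across genes, which are not independent replicates, the responses of bright genes in WT and the pair labelled FceRIa KO correlated with r = 0.53 (rho = 0.42), and those in WT and the pair labelled FcRg KO with r = 0.18 (rho = 0.14). Between the pairs labelled FcRg KO and FceRIa KO r was 0.09 and rho 0.26. Over all genes well above background on the 6 arrays, r was 0.44, 0.12 and 0.046 in the same order.

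A response at least 2-fold higher in WT and above that of both labelled knockouts by at least 1 on the log2 scale was seen for 182 genes, and a lower one for 189. Ranked by the smaller of the differences from both, among genes well above background on the 6 arrays and without the 2-fold condition in WT, the 8 highest were Ackr1, a chemokine-binding receptor of venules (3.97 in WT, 0.13 on the pair labelled FcRg KO, 1.09 on the pair labelled FceRIa KO), Il5 (3.93, 0.26, 0.90), Cyp1a1 (3.29, -0.01, -0.67), Mefv (3.16, 0.41, 0.13), Syt10 (2.57, -1.88, 0.01), Lama1 (2.46, -0.46, -0.31), Lrat (1.47, -1.73, -1.14) and Cyp26b1 (1.32, -5.56, -2.93). The 8 lowest by the same ranking were Zbtb16, Dnajb8, Oxct2b (-1.70), Dsg1c (-1.57), Neurod2 (-1.56), Rxfp3 (-1.5), Vmn2r10 (-1.38) and Sprr4 (-0.95, under 2-fold and so not among the 189), and a second Rxfp3 probe gave 0.27. Of the differences, 49.1% were higher in WT, 29.4% with no filter (237 higher, 569 lower), 40.5% with the value table (206 higher, 303 lower), 59.3% with scaling on the median and 93.1% with normexp. Among bright genes there were 115 higher and 12 lower. Against the pair labelled FceRIa KO alone, 217 genes were higher and 232 lower.

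**Figure D3:**
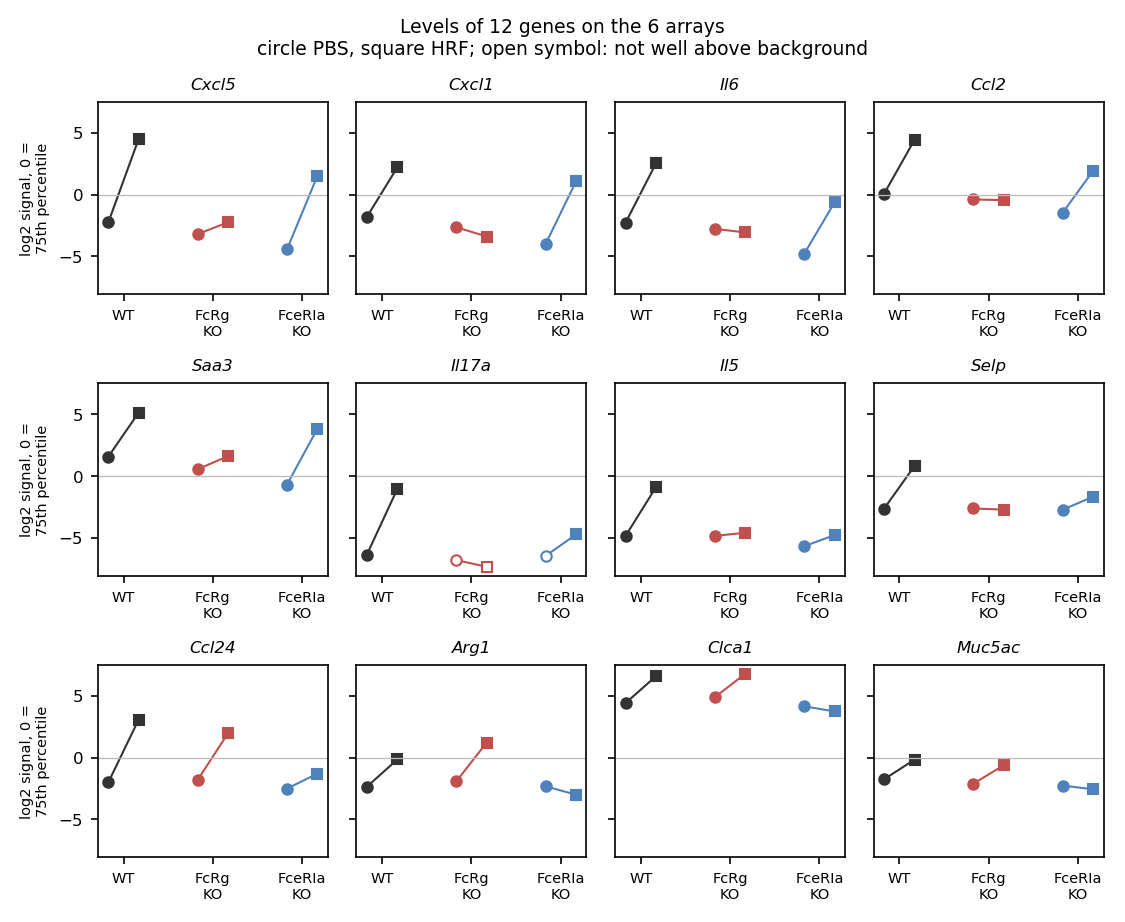
Levels of 12 genes on the 6 arrays, as log2 signal relative to the 75th percentile of each array (y axis) by genotype label (x axis), with circles for PBS, squares for HRF and open symbols where the probe was not well above background. Cxcl5, Cxcl1, Il6, Ccl2 and Saa3 differ between PBS and HRF in WT and on the pair labelled FceRIa KO, and Ccl24, Arg1, Clca1 and Muc5ac, the last drawn after its values were seen, in WT and on the pair labelled FcRg KO. Ccl24 differs on the pair labelled FceRIa KO as well, by less.

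Averaged over the 3 genotypes, no gene passed the threshold for HRF against PBS in limma, with 0 higher and 0 lower, while 1553 genes had an unadjusted p under 0.05. A response that differs between genotypes enlarges the residual of this fit. The test therefore asks what is common to the 3 genotypes, and a count of 0 does not show that HRF had no effect. The smallest p among higher genes belonged to Dcstamp (log2 1.0, SE 0.07), a fusion protein of myeloid giant cells, the growth factor Areg (0.82, SE 0.07) and Aadac (0.81, SE 0.07), each higher in 3 of 3 genotypes with an adjusted p of 0.557. Among lower genes it belonged to Ncam2 (-2.16), Dscam (-1.58) and St8sia3 (-1.43), dim genes with the same adjusted p. With camera's preset correlation, 22 of the 46 lists went up and 3 down. The first included the type 2 list (median 1.08, adjusted p = 1.91e-11) and the NF-kB list (0.77, adjusted p = 3.91e-13), and the second were cardiac muscle (-0.51), smooth muscle (-0.32) and skeletal muscle markers (-0.29). None passed with an estimated correlation, where the lowest adjusted p was 0.476. Adjusted over the list alone, 2 genes rose in each of the mucous and B cell lists and 1 in each of the type 2, ILC2, Fc receptor and basophil lists, and 2 fell in each of the cardiac and skeletal muscle lists.

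B cell genes were almost absent from the arrays labelled FcRg KO. Against WT, the B cell antigen CD20 (Ms4a1) was at least 594-fold lower (limma adjusted p = 0.008) and the IgM receptor Fcmr at least 460-fold lower (0.004), on 2 of 2 arrays. The B cell transcription factors Pou2af1 and Spib fell 37.6-fold and 16.5-fold, Cxcr5 28.6-fold and Ly6d 19.7-fold, and Tnfrsf13c, Fcrl1 and Klhl14 were at least 38.8-fold, 17.4-fold and 8.49-fold lower. The low-affinity IgE receptor Fcer2a fell 7.61-fold (adjusted p = 0.025), and Fcrla, which lies near Fcer1g, 6.56-fold (0.022). In all, 25 genes fell and 1 rose, Arsk (log2 2.23, adjusted p = 0.038), of 17608, with 2362 genes at an unadjusted p under 0.05.

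Of the 15 B cell markers, 8 fell over all genes and 14 adjusted over the list alone, with a median of -3.50, or -3.49 with genes at background at their bound (camera adjusted p = 2.38e-24 with the preset correlation, adjusted p = 0.877 with an estimated correlation). Mzb1 of the plasma cell list fell as well (log2 -2.80, adjusted p = 0.025), and Jchain was at least 74.1-fold lower without passing (adjusted p = 0.092). T cell markers had a median of 0.24, and 0 of 22 were at least 2-fold lower on both arrays. With the preset correlation 6 lists went up and 7 down, and 0 with an estimated one. Inflammatory cytokines (-0.72) and interferon-inducible chemokines (-0.57) were among the lists that went down, and type I interferon genes (0.27) and erythroid genes (0.39) among those that went up. Against WT, inflammatory cytokines stood at -0.17 on the PBS and -1.03 on the HRF array, and interferon-inducible chemokines at -0.19 and -0.80. The highest genes that did not pass were Cox7b2 (adjusted p = 0.134), Serpina1e (log2 1.91, adjusted p = 0.132) and Ica1l (1.54, adjusted p = 0.134). Leaving out any of the 4 arrays of the 2 genotypes leaves 1 array in a group and 1 residual degree of freedom. Such fits, given with the processing below, say little about how stable the calls are. Against WT, the B cell list was low on each array alone, at -3.31 on the PBS array and -3.70 on the HRF array.

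On the arrays labelled FceRIa KO against WT, genes near Fcer1a stood apart. Ifi202b, an interferon-inducible gene, was 43.4-fold higher (log2 5.44, SE 0.18), Atp1a4 23.2-fold higher (4.53, SE 0.23) and Fcer1a 9.90-fold higher, each on 2 of 2 arrays, and none passed (limma adjusted p = 0.075 each). Aim2 (1.44) and Kcnj10 (1.36) were higher, and Dusp23 (-2.09), Ifi211 (-1.83), Gm4847 (-1.54) and Ifi208 (-1.47) lower, on both arrays within 10 Mb of Fcer1g or Fcer1a. B cell markers had a median of 0.07. No gene passed in limma, with 0 higher and 0 lower and 2264 at an unadjusted p under 0.05, and the lower genes nearest to passing were the dim Olfr270, Olfr1352 and Olfr979. Without the challenge term, 4 genes rose and 69 fell. With the preset correlation 10 lists went up, among them neutrophil markers (0.29) and alveolar type 1 cell markers (0.22), and 9 down, among them type 2 genes (-0.95), mucous genes (-1.01) and interferon-inducible chemokines (-0.79), and the lowest adjusted p with an estimated correlation was 0.925. These averages include the HRF response: against WT, the type 2 list stood at -0.09 on the PBS array and -1.32 on the HRF array, the mucous list at -0.44 and -0.99, and interferon-inducible chemokines at -0.59 and -0.91.

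**Figure D4:**
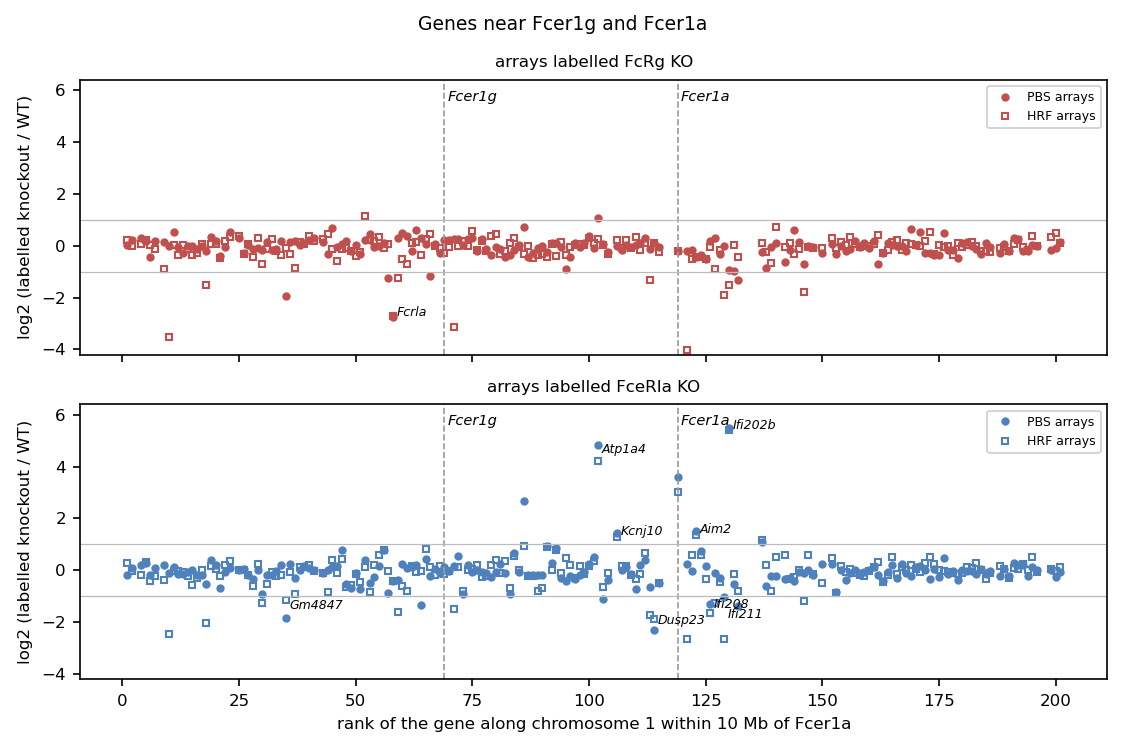
Log2 ratio to WT (y axis) of 182 genes with a mean log2 of -6 or more within 10 Mb of Fcer1a, in gene order along chromosome 1 (x axis), on the arrays labelled FcRg KO (upper panel) and FceRIa KO (lower panel), with filled circles for the PBS arrays and open squares for the HRF arrays. Grey lines mark a 2-fold difference and dashed lines Fcer1g and Fcer1a, and Ifi202b lies at 5.48 and 5.40 on the PBS and HRF arrays labelled FceRIa KO.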

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

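All tests of explanations in this part were chosen after the results were seen. HRF to PBS ratios that went opposite ways between genotype labels are listed here as differences of log2 ratios, the first-named genotype minus the second. Each comes from 1 pair of arrays per genotype and was not tested. Between WT and the pair labelled FcRg KO, Cyp26b1 differed by 6.88, Syt10 by 4.45, Cxcl9 by 3.41, Lrat by 3.19 and Prg4 by 2.49. Between WT and the pair labelled FceRIa KO, Cyp26b1 differed by 4.25 and Lrat by 2.61. Between the pairs labelled FcRg KO and FceRIa KO, Ucp1 differed by -9.20, Cidea by -4.41, Cxcl9 by -4.02 and Prg4 by -2.39. Ucp1 and Cidea belong to the adipocyte list, which stands for a neighbouring tissue. Against WT, that list stood at 0.47 and -0.49 on the PBS and HRF arrays labelled FcRg KO, and at -0.28 and 0.65 on those labelled FceRIa KO. How much fat each sample held was not measured, so these 2 differences need not be responses to HRF. A second Prg4 probe gave -0.36 in WT where the probe used gave 1.21.

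List medians went opposite ways as well, and these differences were not tested. Between WT and the pair labelled FcRg KO they were 0.63 for T cell markers, 0.58 for immediate early genes, 0.38 for hypoxia and stress response genes, -0.39 for ciliated cell markers, -0.61 for erythroid genes and -0.61 for platelet genes. Between WT and the pair labelled FceRIa KO they were 0.53 for NK cell markers, -0.26 for glucocorticoid response genes, -0.92 for platelet genes and -1.20 for adipocyte markers. Between the pairs labelled FcRg KO and FceRIa KO they were 0.84 for cell cycle genes, 0.65 for NK cell markers, 0.43 for erythroid genes, -0.39 for hypoxia genes, -0.44 for T cell markers, -0.73 for immediate early genes and -2.25 for adipocyte markers.

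Probes with no gene name here were outside the comparisons of the report. Of 21705 compared in WT, 211 were at least 2-fold higher and 1119 lower on the HRF array, against 262 and 130 of 18305 on the pair labelled FcRg KO and 368 and 302 of 17362 on the pair labelled FceRIa KO, and these differences were not tested.

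B cell genes were lower on the arrays labelled FcRg KO. Less lymphoid tissue in the lungs sampled is argued against by T cell markers, whose median stood at 0.24 above WT, with members from -1.21 to 0.77. The T cell list stood at 0.54 against WT on the PBS array and -0.01 on the HRF array. Mice of a B cell deficient line under another label are a candidate explanation: among bright genes at least 1.5-fold off WT, a limit chosen after the data were seen, the share near Ighm lay at percentile 99.4 of all centres, and near Fcer1g at 66.1. Without genes past the limma threshold, such as the B cell gene Serpina9 in that window, it lay at 99.4 as well. In that window Zfp386 (-0.92 and -0.80 on the PBS and HRF arrays) and Vipr2 (1.13 and 1.03) differed alike on both. Serpina3f stood at -0.90 and -3.69, but was also low on the arrays labelled FceRIa KO (-1.17 and -3.08). With all bright genes, the share around Jchain, on another chromosome, was the highest of all centres. On the arrays labelled FceRIa KO the highest was around Sult1d1, on the same chromosome as Jchain. Loss of the FcRg chain stays open, since Fcer1g differed by -0.0400 and its probe may lie outside the deleted part.

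Dim genes made up most of those lower on the WT HRF array. Dim signals raised on the WT PBS array may account for it, but the controls do not decide: the ERCC control probes had a median difference of -0.33 in WT, with 80 of 96 lower on the HRF array, against 0.02 and 0.16 on the pairs labelled FcRg KO and FceRIa KO. The 7 brighter E1A spike-in probes differed by -0.18, 0.32 and 0.37, and relative to them the ERCC probes stood at -0.16 in WT, -0.30 and -0.21, so the contrast between WT and the other pairs depends on the scaling. Without any HRF, 528 genes were lower and 121 higher on the PBS array labelled FcRg KO than on WT PBS. On that labelled FceRIa KO, 501 were lower and 93 higher. Between the PBS arrays of the 2 labelled knockouts, 195 were higher and 189 lower. Among bright genes, 80 and 40 were lower than on WT PBS. An excess of lower dim genes against WT PBS thus also appeared without the challenge, which goes with dim signals raised on that array. For bright genes, loss of transcripts with the challenge stays open, since 45 were lower, within the 23 to 80 seen between PBS arrays.

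Cytokine and chemokine genes had smaller responses on the pair labelled FcRg KO than in WT, although its chemokine list lay above the random lists. Levels already high on its PBS array are argued against by the chemokine list, which stood there at -0.43 relative to WT PBS, close to the -0.41 on the PBS array labelled FceRIa KO. A weaker challenge of the lung or lungs on that HRF array stays open. Of 29 bright type 2 and mucous genes, 0 had a response above WT by 1 or more. The dim genes Tff1 (3.38 against 1.48) and Mmp12 (2.67 against 0.85) did. Eosinophil markers had a higher median there (0.59) than in WT (0.28), and against WT the list stood at 0.12 on the PBS and 0.33 on the HRF array, from 1 array each. The genotype of those mice stays open as well. The chemokine response in WT exceeded theirs by 1.43 in the median, against 0.13 for the pair labelled FceRIa KO. With 1 pair of arrays, genotype and the lung or lungs sampled cannot be told apart.

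For the average HRF effect in limma, the real split of the 6 arrays into 3 and 3 gave 0 genes past the threshold, with 1553 at an unadjusted p under 0.05. The highest of the other splits gave 8, and the 10 splits are too few for a share under 0.05. Against a count of 0 each split gives as many by construction, so this comparison decides nothing. Genotype is a model term, so a split that parts 1 pair reflects the difference within that pair, with 8 genes for the pair labelled FceRIa KO, 3 for WT and 0 for the pair labelled FcRg KO.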

How the results depend on the processing

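The bright genes, the other PBS array, the comparison of WT with the pair labelled FceRIa KO alone and leaving out single arrays for the genotype differences were chosen after seeing the data. Over all alternatives, 782 list medians kept their direction and their side of the random range, 23 moved inside it, 21 moved outside it and 2 reversed. Of 816 ratios of named genes per alternative, 69 moved with normexp, 15 with the mean of all probes, 8 with no filter, 8 with the deposited value table and 0 with scaling on the median. Unless stated, the cause was not tested.

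With normexp and quantile normalization, 35 genes were lower in WT, 26 higher and 80 lower on the pair labelled FcRg KO, 116 higher and 16 lower on the pair labelled FceRIa KO, and 10 lower in WT than in both. Against WT, 5 genes rose and 38 fell on the arrays labelled FcRg KO and 2 rose on those labelled FceRIa KO. With the deposited value table the lower genes were 538 in WT, 300 on the pair labelled FcRg KO (227 higher), 155 on the pair labelled FceRIa KO and 303 in WT against both, and 0 genes rose and 11 fell on the arrays labelled FcRg KO against WT. The alveolar type 1 list on the pair labelled FceRIa KO reversed from -0.04 to 0 there and to 0.010 with scaling on the median.

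Filters on dim probes change the counts by their construction, through the genes they admit. With probes well above background on each array compared, 186 genes were lower in WT, 34 on the pair labelled FceRIa KO and 49 in WT against both. With no filter, 921 were lower in WT, 484 higher and 509 lower on the pair labelled FcRg KO, 589 higher and 306 lower on the pair labelled FceRIa KO, and 569 lower in WT than in both, while 0 rose and 16 fell on the arrays labelled FcRg KO against WT. Among bright genes, 45 were lower in WT, 31 higher and 86 lower on the pair labelled FcRg KO, 115 higher and 11 lower on the pair labelled FceRIa KO, and 115 higher and 12 lower in WT than in both. Against the PBS array labelled FceRIa KO, 590 genes were higher and 149 lower on the WT HRF array.

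For the arrays labelled FcRg KO against WT, 0 genes rose with the mean of all probes, 2 rose and 43 fell without the challenge term, and 8 rose and 41 fell with a trended robust prior. For those labelled FceRIa KO, 4 rose and 69 fell without the challenge term and 2 rose with the trended robust prior. Leaving out the WT PBS, the WT HRF or either array labelled FcRg KO gave from 0 to 0 genes each way for FcRg KO against WT, with 1 residual degree of freedom and the lone array assumed to vary like the others. The average HRF effect gave 0 genes in limma under each alternative run, with between 833 and 1988 at an unadjusted p under 0.05. No paired analysis was possible because each group holds 1 array, so no replicate number can serve as a block beyond the genotype term, which already sets each HRF array against the PBS array of its genotype. Signal over background limits the dim genes, which made up 85.3% of the lower and 29.5% of the higher genes in WT.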

Other observations

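Sex-linked genes were given no list median. Xist stood at 0.28 and 0.15 on the WT PBS and HRF arrays, -0.05 and 0.29 on the arrays labelled FcRg KO, and 0.03 and -0.04 on those labelled FceRIa KO. Eif2s3y, on the Y chromosome, stood at -1.79, -1.92, -1.32, -1.46, -1.46 and -2.14 in the same order, and both were well above background on all 6 arrays. Ucp1 stood at 3.83 on the PBS array labelled FcRg KO, and between -2.61 and 0.82 on the other 5.

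In WT, 14 lists lay within the random range: skeletal muscle (-0.33), oesophagus (-0.30), mast cell (-0.23), nerve (-0.21), thymus (-0.16), fibroblast (-0.07), endothelial (-0.04) and cell cycle genes (-0.03), and lymphatic endothelial (0.01), club cell (0.02), alveolar type 2 (0.05), mesothelial (0.08), germinal centre (0.12) and basophil genes (0.13).

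On the pair labelled FcRg KO, those not given above were thymus (-0.14), mesothelial (-0.11), lymphatic endothelial (-0.10), circadian clock (-0.07), germinal centre (-0.05), complement (-0.04), glucocorticoid (-0.02) and fibroblast genes (-0.01), and endothelial (0.03), alveolar type 1 (0.04), B cell (0.08), monocyte (0.10), mast cell (0.11), club cell (0.13) and plasma cell genes (0.16).

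On the pair labelled FceRIa KO, they were skeletal muscle (-0.14), ciliated cell (-0.05), thymus (-0.02) and mast cell genes (-0.00), and nerve (0.00), germinal centre (0.03), oesophagus (0.03), histamine and lipid mediator (0.04), circadian clock (0.06), ILC2 (0.07), endothelial (0.07), Fc receptor (0.09), plasma cell (0.09), eosinophil (0.11), basophil (0.12) and lymphatic endothelial genes (0.15).

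Of the bright genes within 10 Mb of Fcer1a in the order of assembly GRCm38.p6, 13 of 152 were at least 1.5-fold off WT on the arrays labelled FceRIa KO, percentile 99.1 of all centres, and 2 of 152 on those labelled FcRg KO. The shares over all bright genes were 0.81% and 1.19%.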
